A study of Mus musculus with 17 samples.

How the data were processed

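RNA was measured by strand-specific paired-end sequencing of total RNA from the left and right ventricles of male C57BL/6 mice at postnatal days 0, 3 and 7, in 17 libraries (3 per chamber and age, 2 for RV P7). The values deposited by the authors were RPKM (reads scaled by transcript length and by library size), 1 value per RefSeq messenger RNA entry and library. No header or label names that unit; it was inferred from the values. Low values of an entry were whole multiples of a step, the step fell with transcript length, and the column totals differed between libraries. Whether a read pair was counted as 1 fragment or as 2 reads is not given in the sources used here. Alignment with STAR 2.4.0j and the mouse build mm10 are named per the submitters' processing notes; the counting tool, the annotation version and any filter by the authors are not given in the sources used here. How reads shared by several entries of a gene were assigned is not given either, and 2853 genes had several entries (6739 of 20624). Group means of the Ttn entries at P0 and P7 were at most 0.0932 RPKM, and those of the Ldb3 entries at most 0.396. The value of 1 such entry may therefore leave out shared reads and is not a total of its gene.

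Library sizes were recovered from the values as whole numbers of reads. Whole reads were recovered for 20622 of 20624 entries (99.99%) within a tolerance of 0.02. The recovered libraries held 27561845 to 41061058 reads (median 36153964), of which 16529039 to 29994473 (median 22150822) lay in the listed entries. The share of the library in the listed entries fell with age, at 71.3% ± 1.71 (SD) in LV P0, 62.8% ± 4.16 in LV P3 and 56.5% ± 2.34 in LV P7, and at 70.1% ± 2.39, 61.1% ± 1.13 and 56.2% ± 2.83 in the RV (n = 3 per group, n = 2 for RV P7). Between 9453 and 10130 entries per library reached 1 RPKM, and the 10 highest entries held 12.5% to 15.8% of the RPKM total. All 136 pairs of libraries were checked for duplicates by the variance of their differences over counting noise; it was at least 10.4 times that noise within groups and 13.6 times between groups, so no library repeated another. Names came from a RefSeq gene table of GRCm38.p6 (20379 entries) and, for 76 more, from GENCODE M21; 169 entries stayed unnamed. Coordinates are those of the RefSeq table.

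The design, the gene lists, the naming rule and most alternatives were written before the data were examined, for either counts or normalized values, and the branch for normalized values was used. The 6 groups were the chambers and ages of the labels. Values were taken as log2(RPKM + 1) for entries with at least 1 RPKM in at least 2 libraries (10668 entries). All 17 libraries entered a linear model of the group means with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend) in R 4.3.3. The 11 comparisons were P7 against P0 in each chamber, the steps P3 against P0 and P7 against P3 in each chamber, RV against LV at each age and averaged over the ages with equal weights, and the difference between chambers of the P7 against P0 change. Tests were two-sided, and an entry was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested entries. Recovery and tables used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.

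Of 33 fixed gene lists, 27 had at least 5 tested members and were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists; camera with an estimated correlation was computed beside it. List tests were run for P7 against P0 in each chamber, the chamber comparisons and the difference between chambers; the steps between ages were described by counts of members. The counts adjusted over the list alone apply the adjustment within 1 list. The table holds messenger RNA entries of nuclear genes, so long noncoding RNAs, with H19, Meg3 and Xist, and mitochondrially encoded genes were not analysed here (0 tested members). The skeletal muscle, lung, liver, thymus and brown fat, and Schwann cell and neuron lists had fewer than 5 tested members, and the Y-linked list served as a check of the labels. Genes were named by rule. For the 4 main comparisons these were the 6 highest and 6 lowest log2 changes among called genes with a mean of at least 5 RPKM in the higher group and no overlap between replicates (at 2 or more ages for the averaged comparison, no such condition for the difference between chambers), and 3 and 3 for the other comparisons. To these were added up to 3 called members per list with the largest change and a mean of at least 1 RPKM, and always Myh6, Myh7, Tnni1, Tnni3, Tcap, Nppa, Nppb, Mki67, Cdkn1a, Igf2, Hand1, Hand2, Tbx5 and the Irx genes, of which Irx3 and Irx6 did not pass the filter. Results of some genes that this rule selects are not reported here.

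No label says whether libraries of the same number came from the same animal, so this was checked on residuals from the group means. Within an age, the 8 pairs of LV and RV libraries with the same number correlated at 0.269 to 0.587, libraries of other numbers at -0.402 to 0.0939, and 8 of 8 RV libraries fitted best with their own number. Residuals of a group sum to 0, so these outcomes are not independent. Where libraries of the same number correlate above 0, those of other numbers are pulled below it. Libraries of the same number at different ages correlated at -0.0735 to 0.18 (16 pairs) and were treated as unpaired. The chamber comparisons were therefore also computed with the age and number as a block.

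The test was tested on simulated data made from these libraries, with 200 of 10668 entries changed by known folds. For LV P7 against P0 it recovered 65.7% of 1.5-fold, 97% of 2-fold and 93.9% of 4-fold changes with 5 false calls, for RV P7 against P0 56.7%, 88.1% and 98.5% with 11, for the averaged chamber comparison 98.5%, 95.5% and 97% with 2, and for the difference between chambers 26.9%, 67.2% and 98.5% with 1. With the block the last 2 had 13 and 8 false calls. A mitosis list raised 1.5-fold was called in all 4 main comparisons and 0 of 25 other lists were. The simulated noise was independent between entries, so this does not show how the list test behaves where members vary together. Simulated changes went up and down in equal number, without a general shift of all entries. The false calls therefore do not cover a general shift between ages. Alternatives were quantile normalization, upper-quartile scaling, a pseudocount of 0.1, a filter of 5 RPKM and no filter, limma without trend, only the groups of a comparison, the block, an estimated correlation for lists, and leaving out each replicate in turn. Scaling to the reads in the listed entries, voom weights on the recovered reads and 1 entry per gene were added after the values had been seen.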

Results

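Transcript levels were measured by strand-specific paired-end RNA sequencing in the left ventricle (LV) and right ventricle (RV) of male C57BL/6 mice at postnatal days 0, 3 and 7 (P0, P3, P7). Each of the 6 groups held 3 libraries except RV P7, which held 2, and the labels call them biological replicates. The entry NM_008710 stood at 0.128 to 0.205 RPKM in some P3 and P7 libraries and at 2.99 or more in every P0 library. The libraries thus differed by more than chamber and age, unevenly over the ages, and the bearing on the age comparisons was not tested. Of 20624 RefSeq messenger RNA entries, 10668 passed the expression filter. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y stood above 1 RPKM in all 17 libraries, with Eif2s3y between 25.2 and 48.2 RPKM. Age ordered the libraries along the leading principal component, which held 64.7% of the variance: P0 libraries of both chambers lay between -36.9 and -22.4, P3 libraries between -2.31 and 10.5, and P7 libraries between 27.9 and 33.7. Below, ± after an RPKM value is the SD over the libraries of the group (n = 3, or n = 2 for RV P7), ± after a log2 value is the SE, and every adjusted p is two-sided. The log2 values were taken after adding 1 RPKM, which shrinks the change of genes near or under 1 RPKM. Gene positions are whole-gene GRCm38 coordinates, counted from 1.

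Most fetal-type sarcomere and stress transcripts fell in the LV between P0 and P7. Myh7, the slow beta-myosin heavy chain (chromosome 14, 54970684 to 54994626), fell from 3095 ± 447 to 15.5 ± 0.635 RPKM (log2 = -7.54 ± 0.36, adjusted p = 5.67e-12), 187-fold. Tnni1, slow skeletal troponin I, fell from 267 ± 32.8 to 54.0 ± 1.21 RPKM (log2 = -2.28 ± 0.16, adjusted p = 7.85e-10; 1 of several entries of the gene). Myl4, the atrial and fetal essential light chain, fell from 33.5 ± 8.90 to 1.95 ± 0.474 (log2 = -3.52 ± 0.27, adjusted p = 4.17e-09). The natriuretic peptide Nppa (chromosome 4, 148000722 to 148002074) fell from 791 ± 133 to 214.5 ± 53.3 RPKM (log2 = -1.90 ± 0.29, adjusted p = 1.78e-05). Its neighbour Nppb (chromosome 4, 147985786 to 147987205) fell from 274.5 ± 90.7 to 169 ± 34.2 RPKM (log2 = -0.66 ± 0.27, adjusted p = 0.037), a call that upper-quartile scaling ended (adjusted p = 0.387). Of the 11 tested fetal-type sarcomere and stress genes 9 fell, 1 rose (Acta1) and 1 did not pass; the list median was -1.47 and the list adjusted p = 0.0169, or 0.403 with an estimated correlation. Among 21 adult-type contractile and calcium-handling genes 11 rose and 5 fell (13 and 2 after upper-quartile scaling; list adjusted p = 0.000445, or 0.372 with an estimated correlation). Those that rose included Ckmt2, the mitochondrial creatine kinase of sarcomeric muscle, from 90.4 ± 45.8 to 440.4 ± 14.7 RPKM (2.38 ± 0.28), the M-band protein gene Myom2 (2.09 ± 0.27), Tcap (0.82 ± 0.19), Tnni3 (0.40 ± 0.12) and Myh6 (0.75 ± 0.27; 1 of 2 entries). Those that fell included the sodium-calcium exchanger Slc8a1, the creatine kinase Ckm and the Tnnt2 entry NM_001130174 (-2.90 ± 0.28), 1 of several entries of that gene. Of the other tested Tnnt2 entries, NM_001130175 (-2.05) and NM_001130177 (-2.73) fell too. NM_001130178 (0.07, adjusted p = 0.812), NM_001130179 (-0.10, 0.641) and NM_001130181 (0.11, 0.572) were not called. A gene enters a list by its tested entry with the highest mean, so Tnnt2 counts as a fall by NM_001130174 alone. Of the 24 adult-type genes 21 were tested, and no entry of Ttn or Ldb3 passed the filter.

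Fuel-use genes of the LV moved in opposite directions between P0 and P7. The mitochondrial uncoupling protein gene Ucp3 (chromosome 7, 100472991 to 100486432) rose from 0.0681 ± 0.0377 to 21.1 ± 3.01 (log2 = 4.36 ± 0.17, adjusted p = 5.12e-13). Pdk4, a kinase that shuts down pyruvate oxidation, rose from 12.4 ± 2.67 to 83.0 ± 4.90 RPKM (log2 = 2.67 ± 0.16, adjusted p = 1.14e-10). Of 26 fatty acid oxidation genes 22 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 0.92 and a list adjusted p = 4.34e-25, or 0.0246 with an estimated correlation. Of 20 glycolysis genes 16 fell and 2 rose, with a median of -1.01 (list adjusted p = 0.000632, or 0.372 with an estimated correlation; 12 fell and 3 rose after upper-quartile scaling). The glucose transporter gene Slc2a1 (chromosome 4, 119108745 to 119137330) fell from 57.0 ± 6.77 to 5.08 ± 0.946 RPKM (log2 = -3.26 ± 0.13, adjusted p = 5.12e-13). So did the aldolase gene Aldoc (-3.16 ± 0.12) and Pgam1, from 220.1 ± 29.9 to 50.8 ± 5.63 RPKM (-2.09 ± 0.12). The risers of that list were the insulin-responsive transporter Slc2a4 and the muscle enolase Eno3. Fbp2, the muscle fructose bisphosphatase (chromosome 13, 62836884 to 62858400), rose from 0.0825 ± 0.0311 to 12.5 ± 1.02 RPKM (log2 = 3.63 ± 0.11, adjusted p = 9.1e-15).

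Respiratory-chain genes of the LV showed no common direction that held across scalings. Of 27 nuclear-encoded oxidative phosphorylation genes 4 rose and 2 fell (3 and 0 adjusted over the list alone), but 18 rose and 0 fell after upper-quartile scaling. The list median was -0.002 and its mean 0.07, and it ranked above the other genes (list adjusted p = 0.00165, or 0.412 with an estimated correlation). The muscle-type cytochrome oxidase subunits Cox8b (628 ± 94.9 to 1175 ± 53.5 RPKM; 0.91 ± 0.13), Cox6a2 (0.75 ± 0.18) and Cox7a1 (0.44 ± 0.15) were among those that rose. Of 17 tricarboxylic acid cycle genes 2 rose and 7 fell, against 7 and 1 after upper-quartile scaling (list adjusted p = 0.657). Suclg2 fell (-0.94 ± 0.09), and the falls of Idh2 (-0.57 ± 0.10) and Idh3a (-0.52 ± 0.10) did not pass after upper-quartile scaling (adjusted p = 0.0644 and 0.231). Of 14 hypoxia-response genes 8 fell (7 adjusted over the list alone) and 0 rose, among them Bnip3 (-1.59 ± 0.17) and the pyruvate dehydrogenase kinase Pdk1 (-1.32 ± 0.09), with a list adjusted p = 0.0362, or 0.481 with an estimated correlation.

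Cell-division transcripts fell together in the LV. All 21 mitosis genes fell, including the cyclin Ccnb1 from 66.1 ± 4.2 to 20 ± 2.05 RPKM (log2 = -1.68 ± 0.18, adjusted p = 3.41e-07). Others were the spindle-checkpoint kinase Bub1b (-1.70 ± 0.18), the cytokinesis gene Anln (-1.69 ± 0.19) and the proliferation marker Mki67 (-0.99 ± 0.13). All 21 DNA replication genes fell, 20 of them also after upper-quartile scaling, including the ribonucleotide reductase genes Rrm1 (-1.54 ± 0.12) and Rrm2 (-1.46 ± 0.18) and the helicase gene Mcm7 (-1.36 ± 0.13). The list medians were -1.36 and -1.03, with list adjusted p = 7.35e-07 and 1.5e-06; with an estimated correlation these were adjusted p = 0.382 and 0.372. Among 16 cell-cycle inhibitors 2 rose and 9 fell (list adjusted p = 0.813). The stress-induced Gadd45a rose (1.40 ± 0.16) while Cdkn2d (-1.22 ± 0.18) and Gadd45b (-1.18 ± 0.18) fell, and Cdkn1a stood at log2 = -0.10 ± 0.14 (adjusted p = 0.545). Imprinted growth-related genes fell in 11 of 12 cases (list adjusted p = 0.000419, or 0.372 with an estimated correlation). Among them were the growth factor gene Igf2, from 25.6 ± 3.06 to 9.27 ± 0.973 RPKM (-1.37 ± 0.23; 1 of several entries), Plagl1 (-2.36 ± 0.15), Grb10 (-2.39 ± 0.16; 1 of several entries) and the growth-restraining receptor Igf2r (-2.12 ± 0.18).

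Endothelial, fibroblast, antigen presentation and macrophage markers rose in the LV more often than they fell. Of 12 endothelial markers 8 rose and 0 fell (list adjusted p = 4.21e-09, or 0.042 with an estimated correlation). The lipid-binding Fabp4 rose from 558 ± 133 to 1591 ± 118 RPKM (1.53 ± 0.16), with the junction genes Cldn5 (1.36 ± 0.10) and Cdh5 (1.06 ± 0.10). Of 12 fibroblast markers 7 rose and 1 fell (list adjusted p = 7.35e-07, or 0.0451 with an estimated correlation). The microfibril genes Mfap5 (2.37 ± 0.18) and Mfap4 (1.59 ± 0.14) rose, while the Gsn entry NM_001206367 fell (-2.33 ± 0.12) and NM_146120, the other tested one of 4 Gsn entries, rose by 1.15. Of 23 extracellular matrix genes 11 rose and 2 fell (16 and 1 after upper-quartile scaling; list adjusted p = 3.26e-07, or 0.372 with an estimated correlation). The basement-membrane collagen Col15a1 (1.80 ± 0.14) and elastin, Eln, from 19.8 ± 4.04 to 58.4 ± 11.1 RPKM (1.52 ± 0.23), rose, and the fetal fibrillin Fbn2 fell (-1.75 ± 0.21). Antigen presentation genes rose in 7 of 8 cases, led by the immunoproteasome subunit Psmb8 (1.69 ± 0.21) and the class I gene H2-D1 (1.52 ± 0.15), with a list adjusted p = 3.26e-07, or 0.0246 with an estimated correlation. Macrophage markers rose in 7 of 10 cases and fell in 1 (8 and 1 adjusted over the list alone), with Cx3cr1 at 0.86 ± 0.15 and a list adjusted p = 8.3e-05, or 0.293 with an estimated correlation. Smooth muscle and pericyte markers split, the pericyte gene Rgs5 rising (2.48 ± 0.11) and the smooth muscle calponin Cnn1 falling (-3.22 ± 0.25); 5 of 9 rose and 2 fell (list adjusted p = 0.000776, or 0.0781 with an estimated correlation). Of 10 epicardial markers 6 fell and 1, Aldh1a2, rose (list adjusted p = 0.805). Upk1b stood at -1.47 ± 0.29, Tbx18 at -1.46 ± 0.23 and Krt19 at -1.45 ± 0.25.

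Transcription-factor and signalling lists moved less evenly in the LV. Of 17 chamber patterning genes 13 fell and 2 rose (14 and 2 adjusted over the list alone; list adjusted p = 0.0224, or 0.463 with an estimated correlation). The left-sided basic helix-loop-helix factor Hand1 (chromosome 11, 57828713 to 57832147) fell from 5.33 ± 2.27 to 0.134 ± 0.105 RPKM (-2.43 ± 0.16). The trabecular growth factor gene Bmp10 (chromosome 6, 87428994 to 87434512) fell from 19.3 ± 7.37 RPKM to a value listed at 0. Hand2 (-0.76 ± 0.11), Tbx5 (-0.79 ± 0.14), Irx1 (-1.38 ± 0.19), Irx2 (-1.85 ± 0.22), Irx4 (-0.90 ± 0.11) and Irx5 (-0.62 ± 0.19) fell as well, the last of them not after upper-quartile scaling (adjusted p = 0.103). Of 14 immediate-early genes 6 rose and 3 fell (6 and 4 adjusted over the list alone; list adjusted p = 0.00161, or 0.372 with an estimated correlation). Egr1 stood at 1.38 ± 0.27, Klf4 at 1.01 ± 0.10 and Atf3 at -1.77 ± 0.20. Of 16 hormone and metabolic regulators 5 rose and 6 fell (list adjusted p = 0.101). Klf9 stood at 1.15 ± 0.21, Klf15 at -1.61 ± 0.12 and Igf1r at -1.04 ± 0.17. Of 14 ion channel and gap junction genes 4 rose and 6 fell; the pacemaker channel gene Hcn2 rose (2.42 ± 0.14) while Hcn4 (-1.19 ± 0.16) and Kcnq1 (-0.67 ± 0.10) fell. The median of that list was -0.13 and its mean 0.05 (list adjusted p = 0.0738).

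Ribosomal protein genes fell in 21 of 22 cases in the LV (22 adjusted over the list alone, 16 after upper-quartile scaling; list adjusted p = 0.000476, or 0.44 with an estimated correlation). Rps19 fell (-0.77 ± 0.15). Of 10 atrial markers 6 fell, the light chain Myl7 by the largest amount not already given (-2.04 ± 0.31), and Nr2f1 rose (list adjusted p = 0.46). Interferon-response genes passed as a list (adjusted p = 0.0169, or 0.481 with an estimated correlation and 0.201 after upper-quartile scaling) with 2 of 13 risers, Rsad2 (1.51 ± 0.28) and Ifi27, and a fall of Ifit2 (-0.51 ± 0.13; adjusted p = 0.151 after upper-quartile scaling). Of 12 erythroid markers 1 rose, Slc4a1 (0.59 ± 0.21), and 3 fell, including the embryonic globins Hbb-y and Hba-x (list adjusted p = 0.119). Of 5 lymphoid and granulocyte markers 2 rose and 1 fell, the granulocyte gene S100a8 (-1.09 ± 0.34; adjusted p = 0.0691 after upper-quartile scaling). The skeletal muscle genes Tnni2 (-1.37 ± 0.22) and Mylpf (-1.02 ± 0.18) fell, the brown fat gene Cidea rose (1.41 ± 0.11) and the liver gene Apoa2 fell (-0.38 ± 0.15; adjusted p = 0.418 after upper-quartile scaling). Dbh, the noradrenaline-synthesis enzyme of sympathetic nerves, rose (0.55 ± 0.15). Of the 4 tested Y-linked genes 0 passed.

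Among single genes outside these lists, the LV genes with the largest rises by the naming rule also included the alpha-tubulin gene Tuba8 (chromosome 6, 121210734 to 121226098), from 0.452 ± 0.346 to 37.2 ± 3.29 RPKM (log2 = 4.74 ± 0.23, adjusted p = 7.56e-12). The secretoglobin gene Scgb1c1 (3.82 ± 0.26) and the mitochondrial carrier gene Slc25a34 (3.79 ± 0.14) were others. The largest falls also included the incretin receptor gene Gipr (13.9 ± 2.25 to 0.153 ± 0.0353 RPKM, log2 = -3.68 ± 0.17) and the phosphatase-inhibitor gene Ppp1r1b (44.0 ± 5.54 to 2.77 ± 0.595, log2 = -3.58 ± 0.15). The coregulator gene Cited1, a member of the chamber patterning list, was another (-3.32 ± 0.20, 1 of 4 entries). In all, limma called 6922 transcripts (6754 genes) in the LV at adjusted p under 0.05, of which 5658 were lower and 1264 higher at P7, with 608 and 295 beyond 2-fold. That is 81.7% lower, against 50.9% after upper-quartile scaling, which called 5302 (2698 lower, 2604 higher). The median of all tested transcripts was -0.31 in the LV and -0.29 in the RV with the values as deposited, and -0.02 in both after upper-quartile scaling, so each fall above is to be read against that shift. Of the calls, 3962 in the LV were made in the same direction under both scalings.

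**Figure D1:**
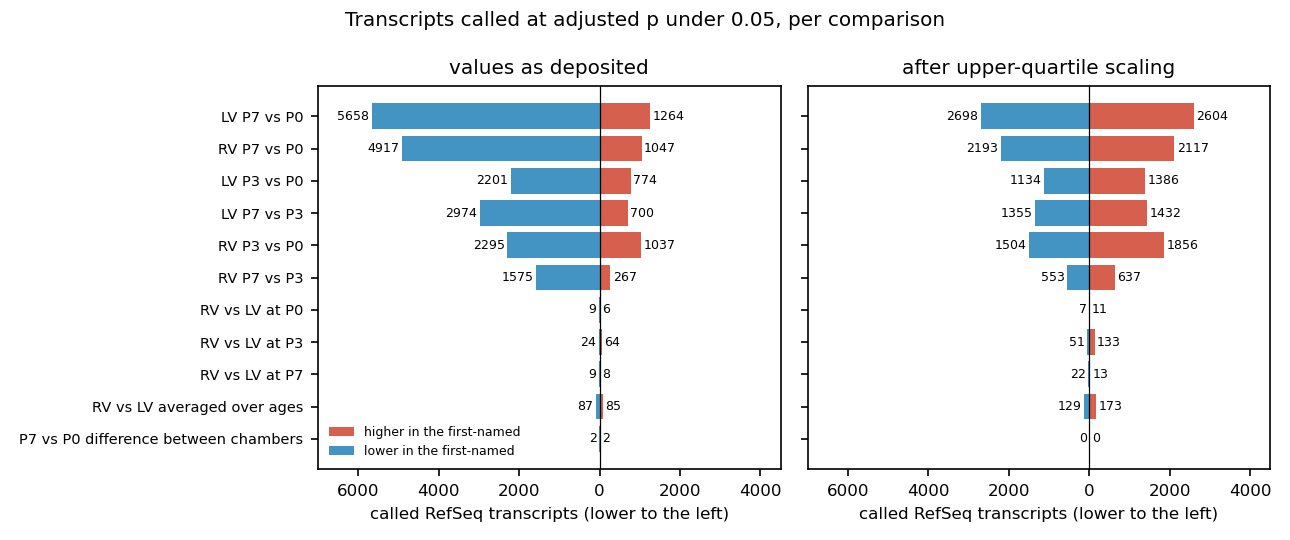
RefSeq transcripts called at adjusted p under 0.05 in each of the 11 comparisons (horizontal axis, number of transcripts, lower to the left and higher to the right; bars, counts), with the values as deposited on the left and after upper-quartile scaling on the right. The LV P7 against P0 bar changed from 5658 lower and 1264 higher to 2698 and 2604.

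Fetal-type transcripts fell in the RV as well between P0 and P7. Myh7 fell from 2953 ± 504 to 14.6 ± 0.316 RPKM (log2 = -7.55 ± 0.40, adjusted p = 6.04e-11), 188-fold. The natriuretic peptides fell steeply, Nppb from 347 ± 88.5 to 43.4 ± 14.5 RPKM (log2 = -2.98 ± 0.30, adjusted p = 2.17e-07) and Nppa from 579.5 ± 81.3 to 78.7 ± 52.4 (log2 = -3.03 ± 0.32, adjusted p = 5.45e-07). The atrial light chain Myl7 fell from 427 ± 92.5 to 37.0 ± 33.0 RPKM (log2 = -3.81 ± 0.35, adjusted p = 7.46e-08). Myl4 fell from 45.8 ± 19.1 to 1.41 ± 0.665 (-4.21 ± 0.30) and Bmp10 from 21 ± 6.67 to 0.0508 ± 0.0719 (-4.34 ± 0.26). Of the 11 fetal-type genes 10 fell and 0 rose, with a median of -2.33 (list adjusted p = 0.000135, or 0.221 with an estimated correlation). Of 21 adult-type genes 10 rose and 5 fell (10 and 6 adjusted over the list alone; list adjusted p = 0.000135, or 0.279 with an estimated correlation). Risers included Ckmt2 (2.63 ± 0.32), Tcap (1.11 ± 0.21), Myh6 (1.01 ± 0.31) and Tnni3 (0.51 ± 0.14). Tnni1 fell from 322 ± 39.2 to 63.3 ± 12.1 RPKM (-2.33 ± 0.17).

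Fuel-use genes of the RV also moved in both directions. Ucp3 rose from 0.173 ± 0.0581 to 30.3 ± 2.56 RPKM (log2 = 4.74 ± 0.19, adjusted p = 2.66e-12). Pdk4 rose from 11.4 ± 2.21 to 106.5 ± 28.6 RPKM (3.11 ± 0.18). Fbp2 (3.87 ± 0.12), Slc25a34 (3.68 ± 0.16), Tuba8 (4.48 ± 0.26) and the glycerol phosphate dehydrogenase gene Gpd1 (3.21 ± 0.17) were also among the largest rises by the naming rule. Of 26 fatty acid oxidation genes 22 rose and 0 fell (median 0.92, list adjusted p = 2.92e-29, or 0.028 with an estimated correlation). Of 20 glycolysis genes 15 fell and 2 rose (16 and 3 adjusted over the list alone; list adjusted p = 0.000157, or 0.257 with an estimated correlation). Slc2a1 fell from 60.1 ± 8.79 to 4.59 ± 0.861 RPKM (-3.45 ± 0.14), with Aldoc (-2.48 ± 0.13) and the lactate dehydrogenase Ldha (-2.22 ± 0.23). Of 14 hypoxia-response genes 9 fell (10 adjusted over the list alone) and 0 rose, led by Slc2a1 and Bnip3 (-1.94 ± 0.19), with a list adjusted p = 0.00248, or 0.357 with an estimated correlation. Of 27 oxidative phosphorylation genes 2 rose and 3 fell (0 and 2 adjusted over the list alone), against 9 and 0 after upper-quartile scaling (list adjusted p = 0.0559, or 0.0041 after that scaling and 0.584 with an estimated correlation), with Cox6a2 at 0.57 ± 0.20 and Ndufs3 at -0.49 ± 0.11 (adjusted p = 0.26 after upper-quartile scaling). Of 17 tricarboxylic acid cycle genes 0 rose and 5 fell, against 7 and 2 after upper-quartile scaling (list adjusted p = 0.313, or 0.0493 after that scaling and 0.786 with an estimated correlation), with Suclg2 at -0.80 ± 0.10 and Sdhb at -0.34 ± 0.10, a fall that did not pass after upper-quartile scaling (adjusted p = 0.932) and turned to 0.11 after quantile normalization. Bex4 fell from 61.2 ± 10.1 to 4.76 ± 2.30 RPKM (-3.48 ± 0.20).

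Division and growth genes of the RV fell. All 21 mitosis genes (median -1.12) and all 21 DNA replication genes (median -0.88) fell, including Cdk1 (-1.47 ± 0.17), Rrm1 (-1.24 ± 0.13) and the primase gene Prim1 (-1.17 ± 0.14). Mki67 fell (-0.64 ± 0.15), though not after upper-quartile scaling (adjusted p = 0.0651). The list adjusted p were 4.37e-06 and 5.13e-06, or 0.357 and 0.337 with an estimated correlation. Of 16 cell-cycle inhibitors 2 rose and 9 fell (list adjusted p = 0.545), Gadd45a rising (1.67 ± 0.18) and Cdkn2d (-1.35 ± 0.20) and Cdkn1c (-1.32 ± 0.19) falling, with Cdkn1a at log2 = -0.31 ± 0.16 (adjusted p = 0.107). Of 12 imprinted growth-related genes 11 fell, including Plagl1 (-2.08 ± 0.16), Igf2r (-2.02 ± 0.21) and Igf2 (-1.54 ± 0.25), with a list adjusted p = 0.000212, or 0.297 with an estimated correlation. All 22 ribosomal protein genes fell (list adjusted p = 4.37e-06, or 0.337 with an estimated correlation), with Rpl19, 1 of several entries, at -1.28 ± 0.25.

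Extracellular matrix, fibroblast and macrophage genes of the RV rose more often than they fell. Of 23 extracellular matrix genes 14 rose and 1, Fbn2, fell, with a list adjusted p = 6.88e-11, or 0.17 with an estimated correlation. Col3a1 rose from 236 ± 29.4 to 528 ± 51.1 RPKM (1.17 ± 0.17), and Col15a1 (1.80 ± 0.16) and Eln (1.57 ± 0.26) rose. Of 12 fibroblast markers 7 rose and 1 fell (8 and 2 adjusted over the list alone; list adjusted p = 1.03e-07, or 0.041 with an estimated correlation). Mfap5 stood at 2.17 ± 0.20, Mfap4 at 1.88 ± 0.16 and the Gsn entry NM_001206367 at -2.32 ± 0.14, while NM_146120 rose by 0.93. Macrophage markers rose in 8 of 10 cases, including Lyz2 (1.29 ± 0.24), Cx3cr1 (1.01 ± 0.17) and C1qa (0.91 ± 0.17), with a list adjusted p = 1.01e-07, or 0.0974 with an estimated correlation. Antigen presentation genes rose in 6 of 8 cases (list adjusted p = 6.07e-06, or 0.041 with an estimated correlation). Psmb9 stood at 1.12 ± 0.21 and H2-D1 at 1.04 ± 0.16. Of 12 endothelial markers 6 rose and 1 fell (list adjusted p = 1.14e-05, or 0.112 with an estimated correlation). Fabp4 stood at 1.25 ± 0.18 and Cldn5 at 0.88 ± 0.11. Of 9 smooth muscle and pericyte markers 5 rose and 2 fell (list adjusted p = 0.000267, or 0.0676 with an estimated correlation). Rgs5 stood at 2.31 ± 0.12 and Cnn1 at -3.01 ± 0.28. Of 10 epicardial markers 2 rose and 4 fell (2 and 7 adjusted over the list alone), the retinoic acid enzyme gene Aldh1a2 rising (1.40 ± 0.12) and Krt19 falling (-1.15 ± 0.28), with a list adjusted p = 0.565. Of 12 erythroid markers 2 rose and 7 fell, among them Hbb-bt (-1.18 ± 0.30), a close paralog of Hbb-bs (list adjusted p = 0.758). Of 5 lymphoid and granulocyte markers 2 rose and 2 fell (list adjusted p = 0.293). S100a8 stood at -1.50 ± 0.38 and S100a9 at -0.87 ± 0.27 (adjusted p = 0.108 after upper-quartile scaling).

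Regulators of the RV moved in mixed directions. Of 17 chamber patterning genes 12 fell and 2 rose (list adjusted p = 0.0572, or 0.0129 after upper-quartile scaling and 0.552 with an estimated correlation). Hand1 fell from 1.05 ± 0.0587 RPKM to a value listed at 0. Hand2 (-0.68 ± 0.12), Irx1 (-0.94 ± 0.22), Irx2 (-1.52 ± 0.24), Irx4 (-0.68 ± 0.12), Irx5 (-0.58 ± 0.21; adjusted p = 0.183 after upper-quartile scaling) and Cited1 (-2.99 ± 0.23) fell, and Tbx5 stood at log2 = -0.32 ± 0.16 (adjusted p = 0.103). Of 16 hormone and metabolic regulators 5 rose and 3 fell, with Klf9 at 1.25 ± 0.24 and Klf15 at -1.35 ± 0.13. The list median was -0.04, its mean 0.09 and its rank higher than other genes (list adjusted p = 0.0107, or 0.357 with an estimated correlation). Of 14 ion channel and gap junction genes 5 rose and 3 fell (list adjusted p = 0.00102, or 0.17 with an estimated correlation). Hcn2 stood at 2.86 ± 0.16. Of 14 immediate-early genes 4 rose and 4 fell (list adjusted p = 0.01, or 0.379 with an estimated correlation), with Egr1 at 1.30 ± 0.30 and Atf3 at -1.94 ± 0.23. Of 13 interferon-response genes Rsad2 rose (1.22 ± 0.32) and Bst2 fell (-0.80 ± 0.25; adjusted p = 0.185 after upper-quartile scaling), with a list adjusted p = 0.0993. Of 10 atrial markers 1 rose and 5 fell (list adjusted p = 0.19). The skeletal muscle genes Tnni2 (-1.41 ± 0.25) and Mylpf (-1.07 ± 0.20) fell, and Cidea (1.23 ± 0.12) and Dbh (0.90 ± 0.16) rose. The limma test called 5964 transcripts in the RV (5829 genes), 4917 lower and 1047 higher at P7, with 484 and 243 beyond 2-fold. That is 82.4% lower, against 50.9% after upper-quartile scaling, which called 4310 (2193 lower, 2117 higher), 3240 of them with the same direction under both scalings. RV P7 rested on 2 libraries, and without RV P7 library 1 the count was 3866.

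**Figure D2:**
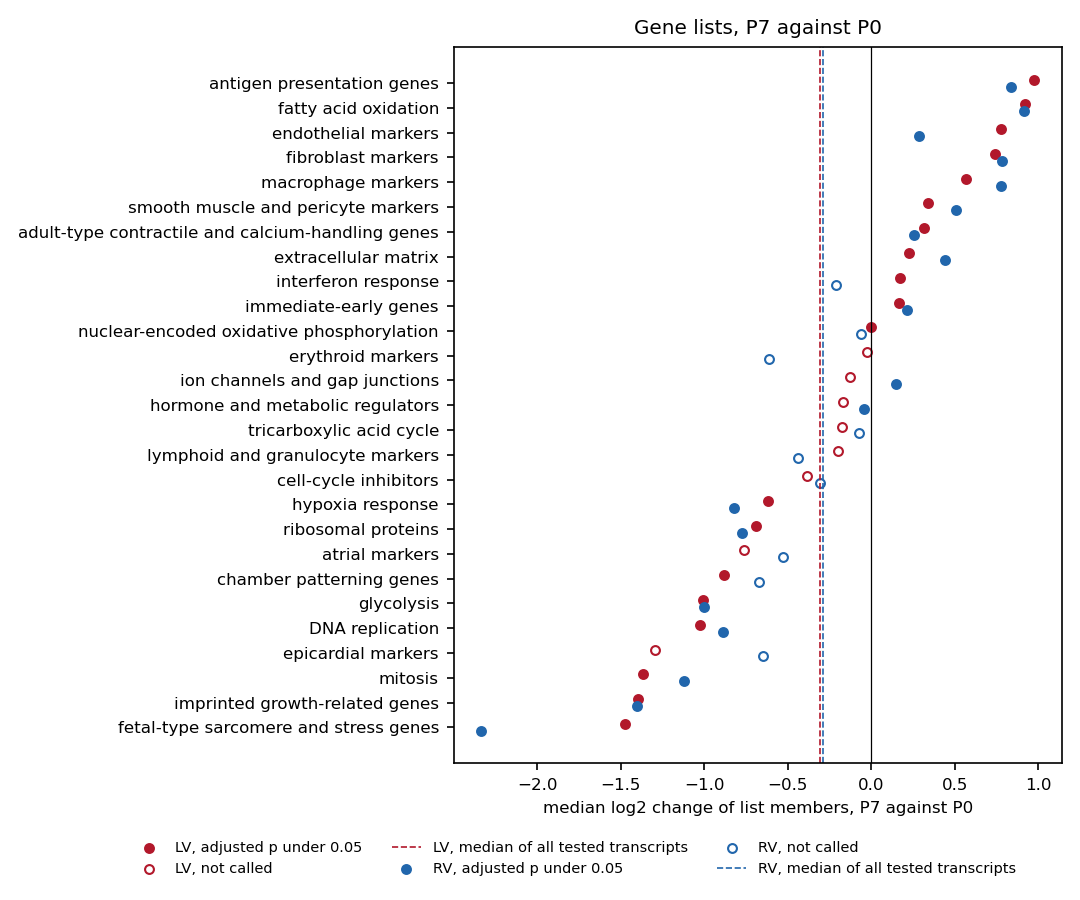
Median log2 change from P0 to P7 of the tested members of each of the 27 tested gene lists (horizontal axis; rows, lists), in LV (red) and RV (blue), filled where the list passed adjusted p under 0.05 with the preset correlation. Dashed lines mark the median of all tested transcripts (-0.31 in LV, -0.29 in RV); the fatty acid oxidation list stood at 0.92 in both chambers and the mitosis list at -1.36 and -1.12.

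The chambers moved the same way over the week. Transcripts lower at P7 in both chambers numbered 4419 (2608 would overlap by independence) and transcripts higher in both 919 (124 by independence), Myh7, Slc2a1 and the mitosis genes among the former and Ucp3 and Fbp2 among the latter. Of 6922 transcripts called in the LV, 6838 (98.8%, exact 95% confidence interval 98.5% to 99%) had the same sign in the RV. Of 5964 called in the RV, 5916 (99.2%, 98.9% to 99.4%) had the same sign in the LV. Those shares include the general shift; after upper-quartile scaling they were 97.7% and 98.5%. Libraries of the same number shared deviations between chambers, so the chambers cannot be taken as independent samples. Whether such libraries came from the same animals is not given by the labels. Several entries of 1 gene could part: 17 of 369 genes with several tested entries in the LV, and 15 in the RV, had entries called in both directions. Among them were Gsn, Ndrg4 and the chemokine gene Cxcl12 in the LV (NM_001012477 at 1.36, NM_021704 at -1.36).

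Many transcripts had moved by P3; the lists are given here by counts of members, without a test of one step against the other. In the LV from P0 to P3, Ucp3 (4.14 ± 0.17) and Fbp2 (3.70 ± 0.11) rose. Myh7 fell to 259 ± 183 RPKM (-3.83 ± 0.36) with Bmp10 (-3.60 ± 0.23) and Gipr (-3.31 ± 0.17). Fatty acid oxidation rose in 26 of 26 genes, while 16 of 20 glycolysis genes, 20 of 21 mitosis genes, 11 of 12 imprinted growth-related genes and 11 of 14 hypoxia-response genes fell; of the DNA replication genes 3 of 21 fell. From P3 to P7 in the LV, 21 of 21 mitosis and 21 of 21 DNA replication genes fell, and Myh7 fell again (-3.71 ± 0.36). In the same step 12 of 26 fatty acid oxidation genes fell back (16 lower and 1 higher adjusted over the list alone; 5 lower and 1 higher after upper-quartile scaling). The peptidase inhibitor gene Pi16 (4.45 ± 0.749 to 25.9 ± 3.75 RPKM; 2.31 ± 0.20), Klhdc8a (2.13 ± 0.13) and the carbonyl reductase gene Cbr2 (1.95 ± 0.14) rose in that step, as did 10 of 12 endothelial markers, 7 of 8 antigen presentation genes and 7 of 12 erythroid markers. The compact-layer repressor Hey2 fell from 33.1 ± 3.78 to 7.36 ± 0.839 RPKM (-2.03 ± 0.11).

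In the RV from P0 to P3, Ucp3 (4.54 ± 0.17) and Fbp2 (3.84 ± 0.11) rose. Nppb (-3.56 ± 0.27), Myh7 (-3.48 ± 0.36) and Nppa (-3.28 ± 0.29) fell. Fatty acid oxidation genes rose in 23 of 26 cases, macrophage markers in 10 of 10 and extracellular matrix genes in 14 of 23, while 17 of 20 glycolysis, 21 of 21 mitosis and 6 of 21 DNA replication genes fell. From P3 to P7 in the RV, 14 of 21 DNA replication genes fell and 0 of 21 mitosis genes by the limma test (0 adjusted over the list alone; median -0.14). Ckmt2 rose from 93.9 ± 11.3 to 445 ± 15.6 RPKM (log2 = 2.24 ± 0.32, adjusted p = 0.00016), with Klhdc8a (2.25 ± 0.15), Tuba8 (2.06 ± 0.26) and 8 of 12 erythroid markers. Myh7 (-4.07 ± 0.40) and the complement gene C3 (38.7 ± 11.1 to 7.57 ± 0.146 RPKM; -2.17 ± 0.32) fell.

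Counted per step, limma called 2975 transcripts in the LV from P0 to P3 (774 higher, 2201 lower) and 3674 from P3 to P7 (700 higher, 2974 lower); after upper-quartile scaling these were 2520 (1386 and 1134) and 2787 (1432 and 1355). In the RV it called 3332 (1037 higher, 2295 lower) and 1842 (267 higher, 1575 lower), and after upper-quartile scaling 3360 (1856 and 1504) and 1190 (637 and 553). Among the transcripts called between P7 and P0, such as Myh7 and Fbp2, the median share of the change reached at P3 was 46.9% in the LV (quartiles 30.2% and 64.7%) and 52.4% in the RV (32.4% and 73.4%; 61.6% after upper-quartile scaling). With P3 set to the level of P0 in simulated data (20 draws), transcripts called at the same threshold gave medians of 2.15% (1.76% to 2.8%) and 2.51% (1.99% to 3.12%), far under the observed shares. With all ages set to the level of P0, transcripts passing by chance at an unadjusted p under 0.05 gave 49.3% and 40.1%, because both changes share the P0 libraries; that value applies to chance calls. In the LV 393 of them had passed their P7 level at P3 and 376 stood on the other side of P0, and in the RV 506 and 360. Without RV P7 library 1 the RV P7 against P3 count was 300, without RV P3 libraries 1 and 3 in turn 979 and 905, and without RV P7 library 2 1121. Without LV P0 library 1 the LV P3 against P0 count was 1925, and without LV P3 libraries 1 and 3 in turn the LV P7 against P3 count was 2101 and 2393.

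**Figure D3:**
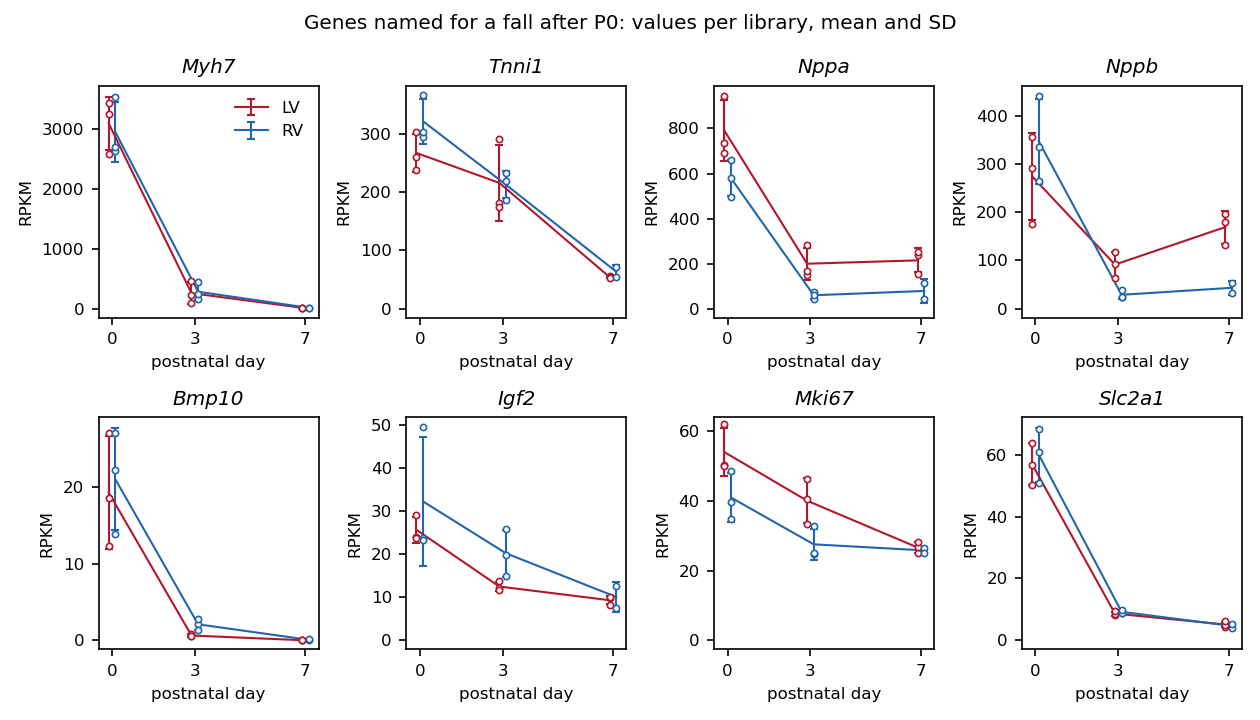
RPKM (vertical axis) against postnatal day (horizontal axis) of 8 genes that fell, LV in red and RV in blue; each point is a library, lines join group means and bars are the SD. Myh7 fell from 3095 to 15.5 RPKM in LV and from 2953 to 14.6 in RV.

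**Figure D4:**
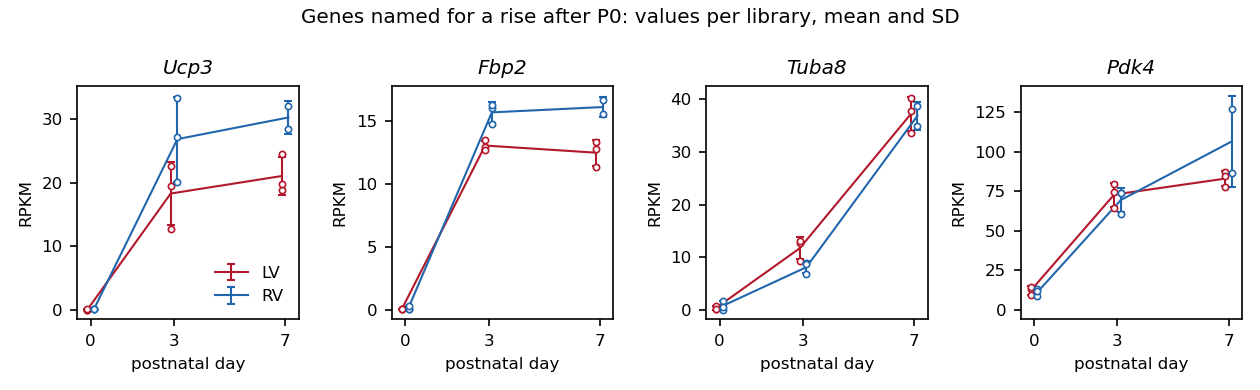
RPKM (vertical axis) against postnatal day (horizontal axis) of 4 genes that rose, LV in red and RV in blue; each point is a library, lines join group means and bars are the SD. Tuba8 rose from 0.452 to 37.2 RPKM in LV.

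Between chambers, averaged over the 3 ages, several epicardial and mesothelial genes were higher in the RV. Msln, a mesothelial surface protein (chromosome 17, 25748613 to 25754378), stood at 16.9 ± 2.57 RPKM in RV P3 against 4.86 ± 0.673 in LV P3 (log2 = 1.15 ± 0.16, adjusted p = 0.000455 over the ages). Uroplakin genes were higher too, Upk3b (log2 = 1.13 ± 0.19, adjusted p = 0.00258) and Upk1b (log2 = 1.08 ± 0.18, adjusted p = 0.00217). The secreted Wnt inhibitor gene Wif1 (chromosome 10, 121034004 to 121100642) was higher in the RV (log2 = 0.92 ± 0.09, adjusted p = 1.42e-05). It stood at 15.5 ± 2.33 against 8.81 ± 1.01 RPKM at P0 and 6.45 ± 1.58 against 2.75 ± 0.413 at P7. Igfbp6 (0.90 ± 0.14), Efemp1 (0.90 ± 0.16) and Eln (0.65 ± 0.14) were higher in the RV. Of 10 epicardial markers 4 were higher and 0 lower (6 and 2 adjusted over the list alone), with a median of 0.54 and a list adjusted p = 1.46e-06, or 0.856 with an estimated correlation; with the paired libraries blocked 6 were higher. In the same comparison 1 of 23 extracellular matrix genes (2 higher and 1 lower over the list alone, 5 and 1 with the paired libraries blocked; list adjusted p = 0.0176, or 0.856 with an estimated correlation) and 1 of 12 fibroblast markers, Dpt (0.26 ± 0.06), were higher. The smooth muscle genes Acta2 (0.46 ± 0.11) and Tagln (0.48 ± 0.09) were higher, and the endothelial marker Cdh5 was lower (-0.25 ± 0.06), though not after upper-quartile scaling (adjusted p = 0.072).

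Natriuretic peptide genes and a few regulators were lower in the RV. Nppa was lower in the RV (log2 = -1.24 ± 0.17, adjusted p = 0.000512), as was Nppb (log2 = -1.08 ± 0.16, adjusted p = 0.000888), though at P0 its mean was higher there (347 ± 88.5 against 274.5 ± 90.7 RPKM, not called), so its average rests on P3 and P7. So were the regulators Hand1 (log2 = -0.90 ± 0.10, adjusted p = 3.32e-05) and Irx1 (log2 = -0.77 ± 0.12, adjusted p = 0.00114). Of 17 chamber patterning genes 3 were lower (5 lower and 2 higher over the list alone), and the list did not pass (adjusted p = 0.225, or 0.856 with an estimated correlation). The axon guidance gene Ntn1 stood at 40.8 ± 4.71 RPKM in LV P0 and 19.1 ± 5.21 in RV P0 (log2 = -0.66 ± 0.08, adjusted p = 0.000143). Sema7a (-0.49 ± 0.07) and the carboxypeptidase gene Cpa1 (-0.70 ± 0.07) were lower in the RV. Of 21 mitosis genes 1, Mki67 (-0.32 ± 0.08), was lower, 11 adjusted over the list alone and 18 with the paired libraries blocked, with a list median of -0.24 and adjusted p = 1.31e-08, or 0.856 with an estimated correlation. DNA replication genes had 0 calls (5 lower over the list alone, 6 with the paired libraries blocked; list adjusted p = 6.31e-05). Fatty acid oxidation (0 calls, 1 higher over the list alone, list adjusted p = 0.00308), glycolysis (0.0464) and oxidative phosphorylation (0.0391, and 0.0771 with the paired libraries blocked) passed as lists in the opposite direction, higher in the RV. Each of these also stood at adjusted p = 0.856 with an estimated correlation. Interferon-response genes (list adjusted p = 0.265, or 0.856 with an estimated correlation) passed as a list with the paired libraries blocked (0.0188). Values that did not pass included Myh7 at log2 = 0.04 ± 0.22 (adjusted p = 0.95), Tnni3 at 0.00 ± 0.07, Cdkn1a at 0.02 ± 0.09, Tbx5 at -0.10 ± 0.09 and Irx4 at -0.06 ± 0.06. With the paired libraries blocked, Myh6 (0.33 ± 0.16; adjusted p = 0.36, blocked 0.00457), Igf2 (0.31 ± 0.14; 0.291, blocked 0.0393), Hand2 (0.18 ± 0.06; 0.179, blocked 0.0492), Irx2 (-0.42 ± 0.13; 0.116, blocked 0.0109) and Irx5 (-0.30 ± 0.11; 0.217, blocked 0.0385) did pass. The limma test called 172 transcripts, 85 higher and 87 lower in the RV, and 302 after upper-quartile scaling (173 and 129). With the paired libraries blocked it called 923 (322 higher, 601 lower), all 172 among them. Without RV P0 library 1 the count was 430, without LV P3 library 2 349, without LV P3 library 3 110, and without RV P7 libraries 1 and 2 in turn 101 and 95.

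**Figure D5:**
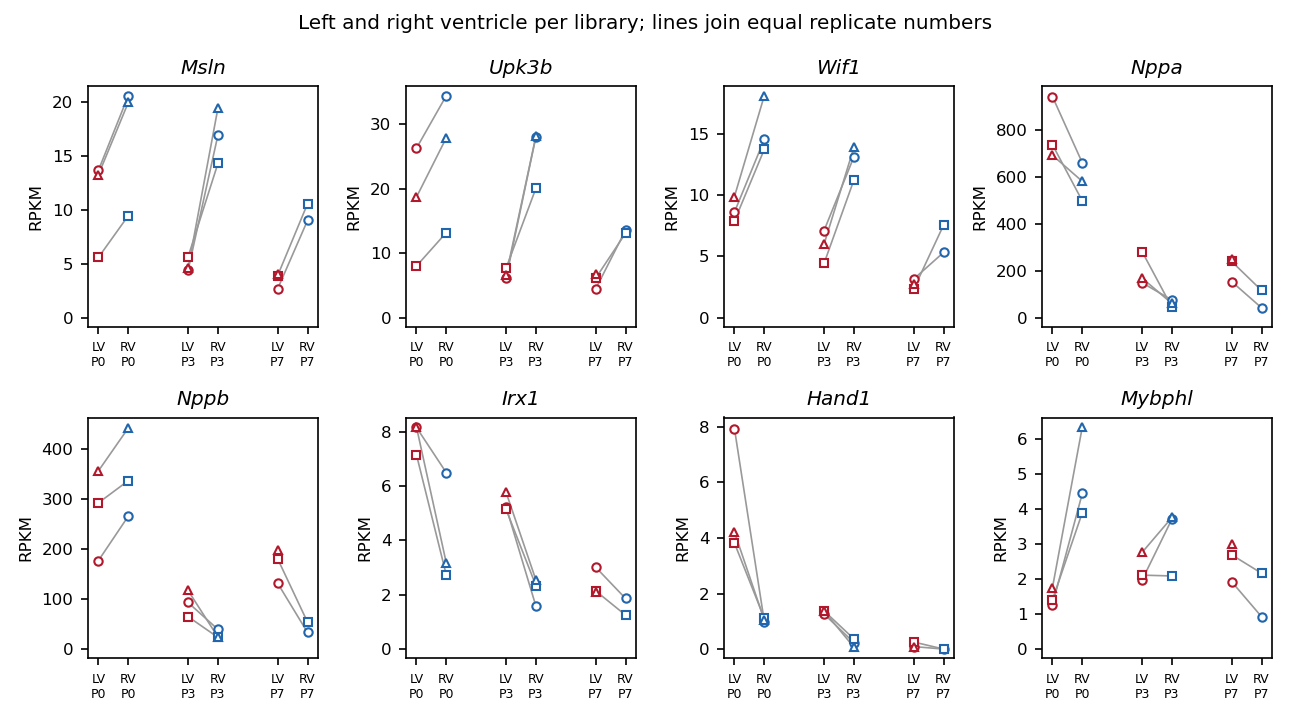
RPKM (vertical axis) of 8 genes in each library, LV in red and RV in blue at each age; grey lines join libraries of the same number and age. Msln stood above the LV in RV P3 (16.9 against 4.86 RPKM on average) and Nppa below it (59.6 against 199.6).

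At P0 few genes passed between the chambers. Hand1 was lower in the RV, at 1.05 ± 0.0587 against 5.33 ± 2.27 RPKM (log2 = -1.57 ± 0.16, adjusted p = 0.000104). Gtsf1 (-1.54 ± 0.30; adjusted p = 0.0511 after upper-quartile scaling) and Gpnmb (-1.99 ± 0.39; 0.0746 after that scaling) were lower too. The calcium-binding Tesc (0.75 ± 0.15) and Oit3 (0.66 ± 0.12) were higher. Myosin light chain, natriuretic peptide and epicardial genes did not pass at P0. As lists, 12 of 27 passed with the preset correlation, led by oxidative phosphorylation (median 0.14, list adjusted p = 1.12e-10), with mitosis (median -0.21, 0.00181) and macrophage markers (median -0.21, 0.00181) below 0; 0 passed with an estimated correlation (smallest adjusted p = 0.814). Epicardial markers (list adjusted p = 0.132, or 0.85 with an estimated correlation) passed with the paired libraries blocked (0.00154), with 4 of 10 higher and 2 lower. In all, 15 transcripts passed limma's test at P0 (6 higher, 9 lower), 98 with the paired libraries blocked (54 and 44) and 18 after upper-quartile scaling. Without RV P0 library 1 the count was 33, without LV P0 library 3 5, without LV P0 library 1 or RV P0 library 2 4, and without LV P0 library 2 or RV P0 library 3 2.

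At P3 the epicardial genes Upk3b (6.76 ± 0.811 in LV and 25.4 ± 4.65 RPKM in RV; log2 = 1.76 ± 0.31, adjusted p = 0.00798) and Msln (log2 = 1.61 ± 0.26, adjusted p = 0.00555) and the complement gene C3 (1.60 ± 0.29) were higher in the RV. Nppa (199.6 ± 71.7 in LV and 59.6 ± 15.5 RPKM in RV; log2 = -1.70 ± 0.29, adjusted p = 0.00654), Nppb (log2 = -1.63 ± 0.27, adjusted p = 0.00555) and Irx1 (-1.03 ± 0.19) were lower. Of 10 epicardial markers 3 were higher (5 over the list alone; list adjusted p = 8e-08, or 0.259 with an estimated correlation) and of 12 fibroblast markers 3 (list adjusted p = 0.000225, or 0.259 with an estimated correlation). Macrophage markers had 0 calls (5 higher over the list alone; list adjusted p = 5.2e-07, or 0.259 with an estimated correlation), and 1 of 23 extracellular matrix genes, Eln, was higher (4 over the list alone; 5.2e-07, or 0.53). DNA replication genes (median -0.28, list adjusted p = 3.26e-09, or 0.454 with an estimated correlation) and the tricarboxylic acid cycle (median -0.14, 9.33e-05, or 0.564) also passed as lists below 0. Oxidative phosphorylation did so (median -0.11, 0.00623, or 0.716) with the values as deposited only (0.0518 after upper-quartile scaling). Of 21 mitosis genes 1, Ube2c, was lower, all 21 adjusted over the list alone and 19 with the paired libraries blocked (median -0.55, list adjusted p = 2.6e-19, or 0.259 with an estimated correlation). The block also called 6 epicardial, 3 fibroblast, 3 macrophage and 9 extracellular matrix genes higher and 9 DNA replication genes lower. The limma test called 88 transcripts at P3 (64 higher, 24 lower), 184 after upper-quartile scaling (133 and 51) and 639 with the paired libraries blocked (326 and 313). Without LV P3 library 2 the count was 210, and without LV P3 libraries 1 and 3 and RV P3 libraries 1 and 2 in turn 33, 34, 52 and 40.

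At P7 the RV held more transcripts of the decarboxylase gene Ddc (7.41 ± 2.23 in LV and 18.7 ± 0.623 RPKM in RV; log2 = 1.26 ± 0.16, adjusted p = 0.00167; 1 of 2 entries), the water channel gene Aqp4 (1.12 ± 0.18) and Wif1 (0.98 ± 0.17). Nppb stood at 169 ± 34.2 RPKM in LV and 43.4 ± 14.5 in RV (log2 = -1.96 ± 0.30, adjusted p = 0.0079), and Cpa1 (-0.82 ± 0.14) and Sema7a (-0.70 ± 0.13) were lower in the RV. Of 12 endothelial markers 0 passed over all genes and 6 were lower over the list alone (median -0.38, list adjusted p = 3.75e-07, or 0.233 with an estimated correlation). Of 10 epicardial markers 0 passed over all genes and 4 were higher over the list alone (list adjusted p = 7.32e-05, or 0.429 with an estimated correlation). Fatty acid oxidation stood above 0 as a list (median 0.11, 6.21e-06, or 0.429) and antigen presentation genes below it (median -0.28, 0.00313, or 0.385), among 9 lists that passed. Interferon-response genes (median -0.30, list adjusted p = 0.0501) and extracellular matrix (median 0.02, 0.155) passed with the paired libraries blocked (4.42e-05 and 0.00256) and stood at 0.763 with an estimated correlation. At P7 limma called 17 transcripts (8 higher, 9 lower), 35 after upper-quartile scaling and 107 with the paired libraries blocked (47 and 60). Without RV P7 library 1 the count was 0 (451 at an unadjusted p under 0.05), without LV P7 libraries 3 and 2 in turn 3 and 6, without LV P7 library 1 10 and without RV P7 library 2 8.

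The change from P0 to P7 differed between chambers at 4 transcripts. Nppb fell further in the RV (difference of log2 changes -2.33 ± 0.40, adjusted p = 0.049), and Hand1 differed the other way (1.39 ± 0.25, adjusted p = 0.049). Both RV P7 libraries listed Hand1 at 0, so the size of its RV fall is set by the 1 RPKM added before the log; with a pseudocount of 0.1 the difference was 1.03 (adjusted p = 0.999). It stood at 5.33 RPKM in LV P0 and 1.05 in RV P0, and at 1.34 and 0.219 at P3. The myosin-binding-protein gene Mybphl (-1.74 ± 0.30) and the phosphorylase kinase gene Phkg1 (1.07 ± 0.19) also passed; both were chosen after their values were seen. Mybphl stood at 4.89 RPKM in RV P0 and 1.54 in RV P7 against 1.47 and 2.53 in LV. Nppa at -1.13 ± 0.44 (adjusted p = 0.855) and Myl7 at -1.77 ± 0.47 (adjusted p = 0.397) did not pass. The limma test called 4 transcripts (2 higher, 2 lower) and 516 at an unadjusted p under 0.05. After upper-quartile scaling limma called 0 (777 at an unadjusted p under 0.05), with Nppb and Hand1 at adjusted p = 0.0553 and 0.07. With the paired libraries blocked limma called 35 (17 and 18), all 4 among them. Without LV P7 library 2 or 3, RV P0 library 2 or 3, or RV P7 library 1 it called 0 (363 to 662 at an unadjusted p under 0.05); without LV P0 library 1 or 2 it called 1, and without RV P0 library 1 2. As lists, 16 of 27 passed the test of the difference with the preset correlation, among them endothelial markers (median -0.29, list adjusted p = 1.29e-07) and fetal-type genes (median -0.52, list adjusted p = 0.00064). With the paired libraries blocked 18 passed, and with an estimated correlation 0 (smallest adjusted p = 0.195).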

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

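In this part, the tests chosen only after the result was seen were the scaling to reads in the listed entries, the limit on atrial tissue from Sln and the comparisons of endothelial and fibroblast with epicardial markers.

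The change from P0 to P7 differed between chambers, by the test of that difference itself, at 4 genes. Nppb (-2.33, adjusted p = 0.049) fell further in the RV, Mybphl (-1.74, adjusted p = 0.049) went down there and up in the LV, and Hand1 (1.39, adjusted p = 0.049) and Phkg1 (1.07, adjusted p = 0.049) differed the other way. Hand1 was listed at 0 in both RV P7 libraries, so its difference rests on the added 1 RPKM and shows no larger proportional fall in the LV. The difference was also past the test with the preset correlation for 16 gene lists, given as the median log2 difference with the list adjusted p. It was below 0 for fetal-type sarcomere and stress genes (-0.52, 0.00064), endothelial markers (-0.29, 1.29e-07), erythroid markers (-0.35, 0.00817), antigen presentation genes (-0.25, 0.00772), ribosomal proteins (-0.15, 0.00652) and atrial markers (-0.14, 0.0228). Smaller medians below 0 were those of immediate-early genes (-0.14, 0.0284), hypoxia response (-0.0677, 0.0475) and oxidative phosphorylation (-0.0453, 0.00652). It was above 0 for epicardial markers (0.49, 0.0228), extracellular matrix (0.26, 0.0284), ion channels and gap junctions (0.25, 0.00652) and chamber patterning genes (0.21, 0.0146). It was also above 0 for mitosis (0.21, 0.00652), DNA replication (0.19, 0.0111) and macrophage markers (0.18, 0.00652). With an estimated correlation none of these 16 lists passed (smallest adjusted p = 0.195, endothelial markers). With the paired libraries blocked 18 lists passed at the preset correlation.

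Far more transcripts were lower than higher at P7 than at P0 in the LV (81.7% of those called), and 3 technical explanations were weighed. A difference in library size is argued against, since with every library thinned to the smallest 81.89% of calls were lower. A few abundant transcripts among the listed entries taking more of the reads are argued against too. With the 10 highest entries of each library taken out of its size the median change was -0.34 against -0.31. Abundant transcripts outside the listed entries were out of reach of that test and belong to the share weighed next. A growing share of reads outside the listed entries cannot be told apart from a general loss of messenger RNA per cell with age. Scaled to the reads in the listed entries 52.94% of the calls were lower, but that scaling centres the changes (median -0.034) and so decides neither. What those other reads were was not tested.

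From P0 to P7 Nppb fell further in the RV than in the LV, and Mybphl went from 4.89 to 1.54 RPKM in the RV and from 1.47 to 2.53 in the LV. Atrial tissue in the RV P0 samples stays open. At P0 the RV held more Mybphl than the LV (1.24 ± 0.20, adjusted p = 0.0165), with Myl7 at 0.77, Myl4 at 0.38, Stard10 at 0.35 and Dkk3 at 0.34 without a call, while Nppa stood at -0.45 ± 0.29. The atrial gene Sln was listed at 0 in all 3 RV P0 libraries, and a limit of 3 reads there comes to 0.189% of the excess of Myl7, but Sln stood at no more than 0.122 RPKM in any of the 17 libraries, so no library here shows what atrial tissue would bring. A single RV P7 library is argued against, since at least 79.39% of each difference remained without either of them (Nppb -1.99 and -2.67, Mybphl -1.38 and -2.10). A difference between the chambers in how they mature stays open as an untested biological explanation.

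Epicardial markers were higher in the RV than in the LV, by 0.493 ± 0.113 (SE) on average over the 8 pairs of libraries, and in 8 of 8 pairs (exact p = 0.00781, adjusted p = 0.168 over 27 lists). A lower share of cardiomyocytes in the RV samples, with the other cell types in unchanged proportions, would raise their markers alike. As the whole reason that is argued against. Endothelial minus epicardial markers came to -0.53 ± 0.133 and fibroblast minus epicardial markers to -0.437 ± 0.0924, each below 0 in 8 of 8 pairs. A part in the difference stays open. At P3 the fibroblast, macrophage and extracellular matrix lists were also higher in the RV by camera with the preset correlation (adjusted p = 0.000225, 5.2e-07 and 5.2e-07). The endothelial list was not (0.326), and none passed with an estimated correlation. A thinner wall with more surface per volume in the RV may be the reason, and so may an uneven dissection; neither was tested.

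Other splits of the same libraries were counted by the test of the calls. For LV P7 against P0, 1 of 10 splits of 6 libraries gave as many calls (6922, highest other 0), and so for LV P3 against P0 (1 of 10; 2975, highest other 0), LV P7 against P3 (1 of 10; 3674, highest other 0), RV P3 against P0 (1 of 10; 3332, highest other 0) and RV against LV at P3 (1 of 10; 88, highest other 52). With 10 splits a share under 0.05 cannot be reached. At P0, 3 of 10 splits of the LV and RV libraries gave as many calls as the real 15, the highest 201. That split set LV 1, LV 3 and RV 1 against LV 2, RV 2 and RV 3. It parted the pairs of equal number only in part and points to a structure of the samples at P0. Among the 4 splits that part every pair the highest other count was 0 at P0 and at P3. For the averaged chamber comparison 1 of 100 splits within ages gave as many calls (172, highest other 1), and 1 of 100 swaps within pairs (172, highest other 42), which excludes chance at that level.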

How the results depend on the processing

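Scaling to reads in the listed entries, voom weights and 1 entry per gene were the tests chosen only after the result was seen. Calls of the large comparisons between ages stayed within 1.5 times their count under the settings that keep all libraries, with the exception of RV P7 against P3 (1842 calls, 1190 with upper-quartile scaling). A similar count did not mean the same calls. With upper-quartile scaling 3962 of 6922 calls of LV P7 against P0 kept call and direction, and 3240 of 5964 of RV P7 against P0. The chamber comparisons moved more; except where a block or fewer libraries or genes are named, the cause was not tested. At P0 the 15 calls became 3 with a filter of 5 RPKM, 0 with only the groups of the comparison (547 at an unadjusted p under 0.05) and 9 with voom weights. At P3 the 88 calls became 222 with quantile normalization, 184 with upper-quartile scaling, 183 with scaling to reads in the listed entries and 21 with no filter. At P7 the 17 calls became 35 with upper-quartile scaling, 47 with scaling to reads in the listed entries, 61 with only the groups of the comparison, 26 with voom weights, 11 with a pseudocount of 0.1 and 8 with no filter. Averaged over ages, the 172 calls became 302 with quantile normalization, 302 with upper-quartile scaling, 279 with scaling to reads in the listed entries and 107 with no filter. The difference between chambers went from 4 calls to 0 with upper-quartile scaling, a pseudocount of 0.1, a filter of 5 RPKM, limma without trend, only the groups of the comparison and voom weights, with 350 to 777 at an unadjusted p under 0.05 (smallest adjusted p 0.0553 to 0.109).

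The pairing of chambers raised the counts of all 5 comparisons that involve it. With paired libraries as a block limma called 98 at P0, 639 at P3, 107 at P7, 923 averaged over ages and 35 for the difference between chambers. On simulated data the block also made more false calls, 16 against 2 at P0, 16 against 3 at P3, 13 against 3 at P7, 13 against 2 averaged and 8 against 1 for the difference. Of 30 named results that were not called, the block brought 5 past the threshold, all in the averaged chamber comparison, and it ended no call of 263 named results.

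With an estimated correlation the lists passing went from 19 to 4 in LV P7 against P0, from 18 to 3 in RV P7 against P0, from 7 to 0 in the averaged chamber comparison and from 16 to 0 for the difference between chambers. The averaged chamber comparison also had 4 with quantile normalization and 4 with no filter, and the difference between chambers 9 with no filter. The share of LV calls with the same sign in the RV (98.8%) was 97.7% with quantile normalization, 97.7% with upper-quartile scaling, 97.8% with no filter and 99.1% with a filter of 5 RPKM. The share of RV calls with the same sign in the LV (99.2%) was 98.5%, 98.5%, 98.4% and 99.4% in the same order. The RV change present at P3 (52.4%) was 60.8% with quantile normalization and 61.6% with upper-quartile scaling.

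Leaving out each replicate in turn gave 6060 to 6698 calls in LV P7 against P0, 3866 (without RV P7 library 1) to 6015 in RV P7 against P0, 1925 (without LV P0 library 1) to 2977 in LV P3 against P0, 2101 to 4338 in LV P7 against P3 (2101 and 2393 without LV P3 libraries 1 and 3), and 2591 to 3208 in RV P3 against P0. RV P7 against P3 gave 300 to 1587 (300 and 1121 without RV P7 libraries 1 and 2, 979 and 905 without RV P3 libraries 1 and 3). Chamber comparisons gave 2 to 33 at P0 (33 without RV P0 library 1, 5 without LV P0 library 3, 4 without LV P0 library 1 or RV P0 library 2, 2 without LV P0 library 2 or RV P0 library 3) and 33 to 210 at P3 (210 without LV P3 library 2, 33, 34, 52 and 40 without LV P3 libraries 1 and 3 and RV P3 libraries 1 and 2). At P7 they gave 0 to 10 (0 without RV P7 library 1, 3, 6, 10 and 8 without LV P7 libraries 3, 2 and 1 and RV P7 library 2). The averaged comparison gave 95 to 430 (430 without RV P0 library 1, 349 without LV P3 library 2, 110 without LV P3 library 3, 101 and 95 without RV P7 libraries 1 and 2). The difference between chambers gave 0 to 4 (0 without LV P7 library 2 or 3, RV P0 library 2 or 3 or RV P7 library 1, 1 without LV P0 library 1 or 2, 2 without RV P0 library 1). Same-sign shares ran from 97.5% to 99.4% and from 98.8% to 99.6%, and the change present at P3 from 37.9% to 54.2% in the LV and from 47.7% to 56.9% in the RV. Where 1 library was left in RV P7 it was assumed to vary like the other groups.

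Of 263 named results that were called, 1945 values under other settings kept direction and call, 116 kept direction without the call and 1 reversed (Sdhb in RV P7 against P0, 0.11 with quantile normalization); with a replicate left out 1565 kept both and 167 lost the call. Of the 30 not called, values near 0 reversed in 8 other settings and 40 omissions, and 2 omissions brought a call. Cdkn1a in LV P7 against P0 became 0.0432 with quantile normalization and 0.0608 with upper-quartile scaling. Between chambers, Tnni3 became -0.0834 with quantile normalization and -0.00713 with the block, and Tcap 0.0138 with upper-quartile scaling. For the difference between chambers, Myh7 became 0.0583 with quantile normalization and 0.00539 with the block, and Tnni1 0.0168 with quantile normalization. Omissions gave, averaged between chambers, Myh7 from -0.143 to 0.225, Tnni3 from -0.0299 to 0.0409, Tcap from -0.126 to 0.0871 and Cdkn1a from -0.0494 to 0.0633. They gave, for the difference between chambers, Myh6 from -0.0459 to 0.676, Myh7 from -0.0892 to 0.128, Tnni1 from -0.248 to 0.138 and Tnni3 from -0.0116 to 0.201. Likewise Tcap ran from -0.0259 to 0.614, Igf2 from -0.499 to 0.181, Hand2 from -0.00986 to 0.154 and Irx5 from -0.161 to 0.203. Depth limits low transcripts, and for genes with several entries so may the unknown assignment of shared reads. The pseudocount of 1 shrinks changes at or under 1 RPKM. Entries under 1 RPKM in all but 1 library were not tested, and no entry of Ttn or Ldb3 was.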

Other observations

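The tests of this part were chosen only after the result was seen, except the test of the clock genes. Some transcripts stood above or below both other ages at P3. With the chambers averaged, limma called 273 transcripts higher at P3 than at both P0 and P7, each by its own test, and 109 lower than at both (244 and 185 after upper-quartile scaling, 119 and 69 with and without it). Among the former, picked after their values were seen, were the thioesterase gene Acot1, at 11.3, 57.6 and 21.4 RPKM over the ages in the LV (-1.37 ± 0.16 from P3 to P7), and the desaturase gene Scd4, at 4.16, 58.7 and 35.3 (-0.66 ± 0.09). Of 26 fatty acid oxidation genes 26 rose to P3 and 13 stood above both other ages (4 after upper-quartile scaling). As a list they rose to P3 by camera with an estimated correlation (p = 0.000452, adjusted p = 0.0122), but the step from P3 to P7 did not pass (p = 0.858), so whether the list peaked at P3 stays open.

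Haemoglobin transcripts stood below both other ages at P3. Hba-a1 stood at 765, 211 and 759 RPKM over the ages in the LV and at 844, 213 and 535 in the RV (-1.90 ± 0.13 to P3 and 1.58 ± 0.13 from there to P7), and Hbb-bs did the same (-1.84 and 1.26); paralogs of each share much of their sequence. Of 12 erythroid markers 10 fell to P3 and 8 rose after it, and 7 stood below both other ages, also after upper-quartile scaling. As a list, with an estimated correlation, neither the fall (adjusted p = 0.286) nor the rise (p = 0.0165, adjusted p = 0.0893) passed over the 27 lists. The single genes Oxct1 (-1.16 ± 0.09 and 0.58 ± 0.10) and Gapdh (-0.90 ± 0.08 and 0.37 ± 0.08) also fell and rose. Of 20 glycolysis genes 17 fell to P3, but 4 rose and 7 fell after it, and 2 stood below both other ages (3 after upper-quartile scaling).

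Interferon-response genes varied between libraries of the same age. At P0 Isg15 stood at 0.805, 12 and 2.01 RPKM in LV libraries 1, 2 and 3 and at 1.11, 9.25 and 3.10 in the RV libraries of the same numbers, and Usp18 at 0.425, 3.69 and 0.412 in the LV and 0.394, 2.65 and 0.574 in the RV. An animal's interferon level may be shared by its chambers, which the test leaves open. Over the 8 pairs the list means, as deviations from their groups, correlated at r = 0.99 (rho = 1.0; exact permutation p = 0.0139, the smallest that the 72 permutations within ages can give; r = 0.976 without the 2 farthest pairs). Over the 27 lists tested this way the adjusted p was 0.188. Chamber patterning genes reached the same p (r = 0.868, or 0.974 without the 2 farthest pairs). Mitosis genes were also alike (r = 0.903, or 0.753 without those pairs, permutation p = 0.0417). Erythroid markers correlated at r = 0.951 (permutation p = 0.153), but at -0.0673 without the 2 farthest pairs. No label identifies the animals, and the pairs were inferred from residuals of all genes, these included.

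Whether clock output genes rise together from P0 to P7 was a test planned in advance, and the list did not pass. It pointed upward in both chambers, with p = 0.106 in the LV and 0.0701 in the RV by camera with an estimated correlation. By the rule set in advance this counted against a joint rise. A test of 7 genes that does not pass cannot show that such a rise is absent. Of 7 tested genes 4 rose and 1 fell in the LV, and 4 rose and 2 fell in the RV, with Dbp at 0.94 and 1.05 and Per2 at -0.75 and -0.62.

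The transcript NM_008710, which the tables used here do not name, split the P3 and P7 libraries by something other than chamber and age. It stood at 14.6 RPKM in LV P3 library 1 and 9.19 in RV P3 library 1 against 0.128 to 0.163 in the other P3 libraries, and at 3.19 and 7.26 in LV P7 and RV P7 library 1 against 0.174 to 0.205 in the other P7 libraries, while all P0 libraries held 2.99 to 15.6. Low values occurred at P3 and P7 only, so what split the libraries was not balanced over the ages. Its bearing on the comparisons between ages was not tested.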
